A study of Trichoplusia ni with 4 samples.

How the data were processed

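Small RNA libraries were made from cultured Trichoplusia ni cells with a barcoded protocol and sequenced on an Illumina HiSeq in a single lane, per the labels' protocols. The labels name 4 samples, each a group of 1, and 3 of them were not used here. Groups were taken from the source names in the labels. With 1 library there were no replicates, no comparison between groups and no p-value between groups.

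The authors deposited raw read counts per distinct read sequence, without normalization, per the note deposited with the series. Per the same note, reads were annotated with bowtie2 against the FlyBase release of the Drosophila genome and its mRNA and noncoding RNA sets with up to 1 mismatch, and reads without a match were written as none. The version of bowtie2, the adapter trimming and the limits on read length are not given in the sources used here. A further deposited table lists mismatches of matched reads against virus, genome, mRNA, rRNA, tRNA and noncoding RNA sets, per the file headers. Of its 2449 sequences, 1326 were found in the annotation as written and 1123 as the reverse complement, and 2448 had the same count in both. This table covered 99.7% of the genome matches on fly arm 2L and 10.2% of the others, so only its tRNA marks and virus mismatches were used. It gave 0 mismatches for 72.5% of its 1380 virus matches. Positions are those of the deposited annotation, and whether it counts from 0 or 1 is not stated. A gene table of Trichoplusia ni was at hand without sequence, and no gene name was taken from it.

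Each sequence was given to the class listed first, as chosen before the data were examined. Almost every rRNA match is listed after a genome match, so 3 reads remain under rRNA by that choice, and counts over every listing are given beside it. The deposited files name no miRNA. Reads were therefore compared with 45 mature miRNAs of Drosophila, 10 mammalian miRNAs, 10 calibrators and a 19-nt and a 24-nt size marker, all recalled from general knowledge after the reads had been seen. The miRNA families had been fixed beforehand in lists, except miR-79, with 264 reads, which is in none of them. The choice of arms and of near copies was made afterwards. A match required identity at those of bases 2 to 8 that the read covers, and at most 2 mismatches over the first 18 aligned bases. It also required a shift of the 5' end of at most 2 bases and at least 16 aligned bases. A read that starts 2 bases inside the sequence lacks base 2 and was still accepted. Tested on simulated data, 1340 of 1340 reads of listed RNAs were assigned to the right kind and 0 of 20000 random reads were assigned. The simulated reads came from the listed sequences themselves, and the kind was scored, not the single miRNA. Random reads do not stand in for other moth RNAs. The test therefore does not show how often moth miRNAs that differ from the list were missed or given a wrong name. By the rule fixed in advance for files that name no miRNA, the 20 most abundant sequences are named, and the members of the lists are named as well although the files do not name them.

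Shares have exact Clopper-Pearson 95% intervals and counts exact Poisson intervals, which cover counting error only. The depth of 134527 reads gives a limit of 3 reads, 0.00223%, for a count of 0. Because 91.5% of the distinct sequences were read once, single sequences other than the most abundant are poorly measured. Opposite-strand pairs were counted among distinct sequences without a genome, as pairs whose 5' ends are complementary over a given number of bases, and the control used the complement without reversal. In a simulated set with 100 planted pairs, 104 were counted above the control. Overlaps, strands, 3' ends, read errors and the setting without calibrators were added after the data had been seen. Alternatives left out sequences under 10 reads or the most abundant sequence, counted each distinct sequence once, split or left out sequences of several classes, left out rRNA, summed miRNAs by family, took the lists as shares of all reads, kept only reads with 0 mismatches, left out calibrators and size markers, and raised the minimum for arms from 10 to 100 reads. An assembly of reads into longer sequences was tried at several settings and nothing from it was used. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.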

Results

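Small RNAs of cultured cells of the cabbage looper moth Trichoplusia ni, an ovarian line widely used to make recombinant proteins with baculovirus vectors, were sequenced in a study of human ARGONAUTE proteins. The labels name 4 samples of 1 library each, namely RNA from purified human AGO1, RNA from purified human AGO2, total RNA from cells infected with an AGO1 baculovirus and total RNA from uninfected cells. The design sets AGO1-bound against AGO2-bound RNA and infected against uninfected cells. The uninfected library is described here, and the other 3 libraries were not used here, so no comparison between groups was made and no value has a replicate error. The uninfected library held 134527 reads of 78100 distinct sequences, from 16 to 25 nt long. Intervals in brackets are exact 95% intervals, Clopper-Pearson for shares and Poisson for counts, and cover counting error only, because reads copied by PCR are not independent molecules. The limit for a count of 0 was taken as 3 reads, 0.00223% of the library, and the upper bound of the exact interval for 0 reads is slightly wider, at 0.00274%.

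Among the insect miRNAs compared, the most abundant in the uninfected cells was bantam, an miRNA known to promote growth and block cell death, with 6734 reads (6574 to 6897). It made up 43.1% (42.3 to 43.9) of the 15635 reads that matched a list of insect miRNAs, which were themselves 11.6% of the library (11.5 to 11.8). miR-184, conserved across animals, followed with 1657 reads or 10.6% of the miRNA reads. Next came miR-279 with 1434 reads and miR-10, encoded in the Hox cluster, with 1429 reads summed over both arms. Their intervals overlapped (1361 to 1510 and 1356 to 1505). miR-279 was compared for its 3' arm only, and the 5' arm of miR-10 alone had 825 reads (770 to 883). miR-308 had 675 reads, miR-9 had 455, miR-2 had 428, miR-276 had 342, miR-11 had 327 and miR-92 had 310. At the lower end, miR-34 had 19 reads, miR-988 had 12 and miR-33 had 10. miR-1, the miRNA of muscle, had 4 reads (1.09 to 10.2), and miR-993 had 3. No read matched the sequences used for miR-124, the miRNA of neurons, or for miR-125, miR-133, miR-281, miR-282, miR-31, miR-6 and miR-iab-4. Of the 45 insect miRNA sequences compared, 35 had at least 1 read and 31 had at least 10. The sequences are those of Drosophila, recalled from general knowledge and compiled after the reads had been seen, so a share is a share of the matches to this list, and a 0 does not exclude a moth miRNA that differs more. Reads with 0 mismatches over the first 18 bases were 74.5% of the matches, and bantam was 56.0% of these. The rank of miR-279 rests on reads with mismatches, since 100 of its 1434 reads had 0, and miR-308, miR-11, miR-9c, miR-92b, miR-278, miR-100, miR-998, miR-13, miR-988 and miR-33 had no such read, against 806 for the 5' arm and 583 for the 3' arm of miR-10.

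**Figure D1:**
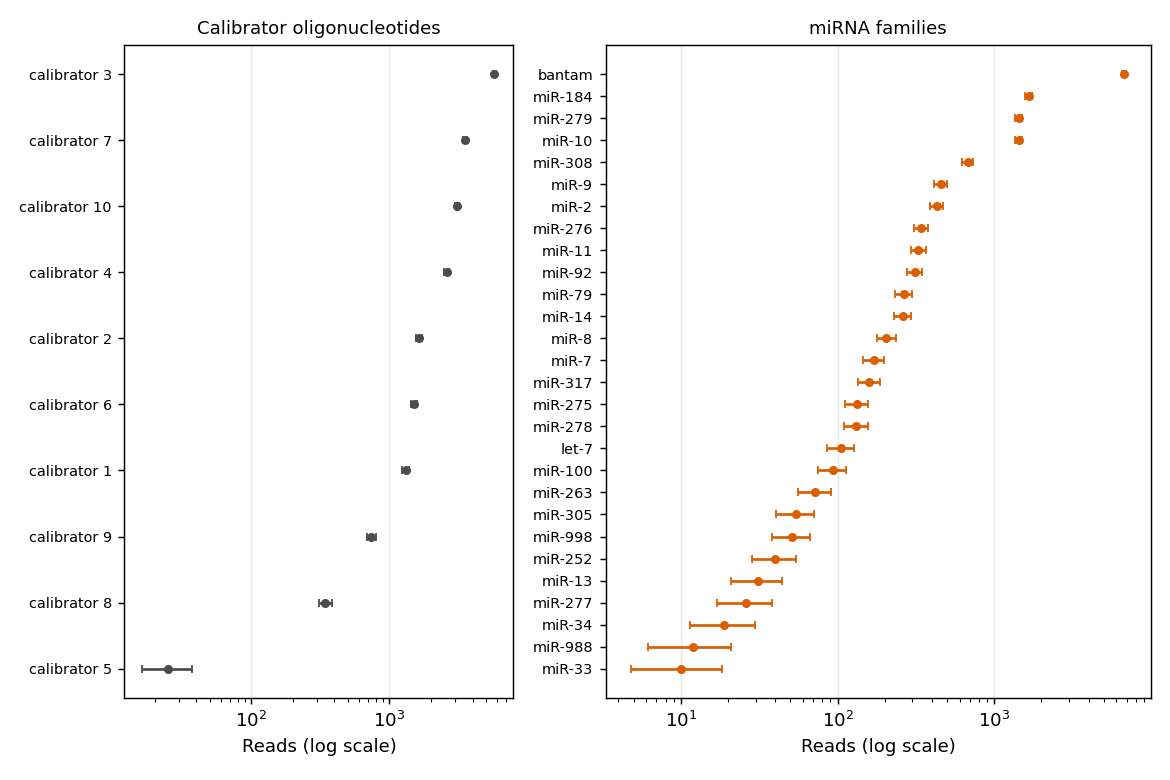
Reads of each synthetic calibrator (left) and each insect miRNA family with at least 10 reads (right) in the uninfected library, on log axes, with exact Poisson 95% intervals as bars. bantam, with 6734 reads, lies above the 1657 reads of miR-184, and the calibrators run from 25 to 5737 reads including those with mismatches that the match rule allows.

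Grouped by lists of miRNAs fixed before the data were examined, the growth and survival list (bantam, miR-14 and miR-278) held 45.6% of the miRNA reads (44.8 to 46.4), with all 3 members at 10 or more reads. The members counted in these lists include those whose reads all had mismatches. Nearly all of it was bantam, as miR-14 had 261 reads and miR-278 had 132. The list of miRNAs conserved across insects held 25.4% (24.7 to 26), with 7 of 10 members at 10 or more reads, led by miR-184 and miR-279. miR-317 had 159 reads and miR-998 had 51 in the same list. The K box family, whose members share a seed, held 9.34% (8.89 to 9.81), with 4 of 5 members at 10 or more reads, among them miR-13 with 31. The Hox cluster list held 9.16% (8.71 to 9.62), of which miR-10 gave all but 3 reads. The ecdysone and metamorphosis list held 4.62% (4.30 to 4.97), with 6 of 7 members at 10 or more reads, including miR-8 with 205 and miR-252 with 40. The list of miRNAs known from neurons held 4.46% (4.14 to 4.79), with miR-9, miR-7 at 170 reads and miR-263 at 72 reads, and without miR-124. The metabolic and fat body list held 2.74% (2.49 to 3.01), with all 5 members at 10 or more reads, among them miR-275 with 133, miR-305 with 54 and miR-277 with 26. The let-7 complex held 1.27% (1.10 to 1.45), with let-7 at 105 reads, miR-100 at 93 and miR-125 at 0. The muscle list held 0.0256% (0.00697 to 0.0655), with 0 of 3 members at 10 or more reads. Several miRNAs stand in more than 1 list, so the shares do not add up, and no sequence was compared for miR-206, miR-iab-8 and miR-183. Among reads with 0 mismatches alone, a setting chosen after seeing the data, the K box family held 2.31% and the neuronal list 2.04%, because miR-308, miR-11, miR-13 and miR-9c had no such read. Reads of the K box members were given to the closest sequence, and those that fit several near-identical members are uncertain.

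Sequences of both arms had reads for 3 miRNAs, and miR-281, also compared for both arms, had 0. miR-10 gave 825 reads from its 5' arm and 604 from its 3' arm, so that 57.7% (55.1 to 60.3) came from the 5' arm. In miR-8 the 3' arm gave 195 reads and the 5' arm 10, a share of 95.1% (91.2 to 97.6). For miR-276, 340 of the 342 reads matched the 3' sequence, 99.4% (97.9 to 99.9). The last listed positions of its main 3' and 5' reads were 10358381 and 10312908 on 3L. A read may be listed at several positions, so these reads are not shown to come from 1 hairpin or from different ones. On the Drosophila chromosome arms to which the deposited annotation assigned them, the main reads of let-7 and miR-100 started at 18472044 and 18471445 on the plus strand of 2L, and those of miR-275 and miR-305 at 7425853 and 7425979 on 2L. Those of miR-34, miR-277 and miR-317 started at 5926674, 5925802 and 5916903 on 3R. These positions lie in the fly genome, not in that of the moth, and the base from which they are counted is not stated. Where a main read had several listed positions, the last is given.

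The single most abundant sequence of the library was not a cell RNA but a synthetic oligonucleotide. TAGCATATCGAGCCTGAGAACA, calibrator 3 of the set spiked into samples in this barcoded protocol, was read 4675 times. Calibrators and size markers together took 20583 reads, 15.3% (15.1 to 15.5) of the library, of which 65 were size markers. The match rule leaves out calibrator reads with a change in bases 2 to 8, so this is an undercount that the interval does not cover. All 10 calibrators were found, with exact reads from 20 for calibrator 5 to 4675 for calibrator 3, a ratio of 234. Against calibrator 8, the next lowest with 246 exact reads, the ratio was 19. The amounts added are not given in the sources used here, and the calibrator sequences were likewise recalled after the reads had been seen.

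The 10 most abundant sequences held 17% (16.8 to 17.2) of the reads, 7 of them calibrators and 3 miRNAs. Among the 20 most abundant, 8 were calibrators, 6 were miRNAs and 6 matched nothing compared here. bantam appeared in 3 lengths that start at 642259 on the plus strand of 3L, the 23-nt TGAGATCATTGTGAAAGCTGATT with 3176 reads, the 22-nt TGAGATCATTGTGAAAGCTGAT with 2700 and the 24-nt TGAGATCATTGTGAAAGCTGATTT with 339. The main miR-279 read, TGACTAGATCTACACTCATTGA, had 982 reads and 1 mismatch to the fly sequence over the first 18 bases, and the main miR-308 read, AATCACAGGATAATACTGCGA, had 520 reads and 1 mismatch over the same length. The main miR-184 read, the 20-nt TGGACGGAGAACTGATAAGG, had 706 reads and started at 9216927 on the minus strand of 2R. Of the sequences left unassigned, TCAGTCTTGTCGAATGGTGG had 960 reads and its longer form TCAGTCTTGTCGAATGGTGGGT had 861, with 407 more for the 19-nt TCAGTCTTGTCGAATGGTG. TCAGGTACTAGGTGACTCTGAG had 863 reads and its 21-nt form TCAGGTACTAGGTGACTCTGA had 541. TCGGTGAATGCCAACGGATTTC had 340 reads. The other calibrators among the 20 were calibrator 7 with 2911 reads, calibrator 10 with 2359, calibrator 4 with 2300, calibrator 2 with 1379, calibrator 6 with 1253, calibrator 1 with 1168 and calibrator 9 with 453.

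By the class the deposited annotation lists first, 86.0% (85.8 to 86.2) of the reads matched nothing, 12.9% (12.7 to 13.1) matched the Drosophila genome and 1.09% (1.04 to 1.15) matched a baculovirus genome. The reads without a match included most of the added oligonucleotides, 17.8% of them, and listed miRNAs, 3.48%, while 78.7% were neither. Most listed miRNA reads were among the fly matches, since 25.8% of them had no Drosophila match. Outside calibrators, size markers, listed miRNAs, rRNA and baculovirus, 4039 reads had a Drosophila match. These held 158 of the 186 distinct sequences at 16 nt, against 224 of 12398 at 21 nt. Matches expected by chance were not computed for the fly genome, so the part of its share due to chance stays open. Counting every class listed for a sequence, rRNA was matched by 1732 reads, 1.29% (1.23 to 1.35), noncoding RNA by 1174 reads, 0.873% (0.824 to 0.924), and mRNA by 148 reads, 0.110% (0.0930 to 0.129). Of the noncoding RNA reads, 974, or 83.0% (80.7 to 85.1), were listed miRNAs already counted above. tRNA, marked only in the second deposited table, was matched by 336 reads, 0.250% (0.224 to 0.278). That table held only 10.2% of the genome matches off arm 2L. The tRNA share is therefore a lower bound, and its interval does not cover the missing part. These references are of a fly, so moth RNAs that differ at more than 1 base are among the unmatched reads. The transcript classes were also filled mainly for fly arm 2L, which gave 74.9% of the sequences with a transcript match against 13.8% of those with a genome match, so these classes are undercounted.

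Reads of 20 nt were the largest length class, with 50506 reads or 37.5% (37.3 to 37.8), followed by 22 nt with 37967 reads or 28.2% (28.0 to 28.5) and 21 nt with 13% (12.8 to 13.2). The miRNAs peaked at 22 nt, with 47.4% of their reads there and 28.6% at 23 nt. rRNA reads peaked at 20 nt with 65.9%, baculovirus reads at 20 nt with 66.8%, and the reads without any match at 20 nt with 50.2%. At 22 nt, 51.9% of the reads were assigned to calibrators, an undercount, since the match rule leaves out those with a change in bases 2 to 8. Without the assigned calibrators and size markers, a setting chosen after seeing the data, the shares became 44.3% at 20 nt and 16% at 22 nt. The 20-nt reads were spread over many sequences, since 76.6% of them came from sequences read once, against 14.1% at 22 nt. With sequences of fewer than 10 reads left out, the 20-nt share fell to 5.92%.

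**Figure D2:**
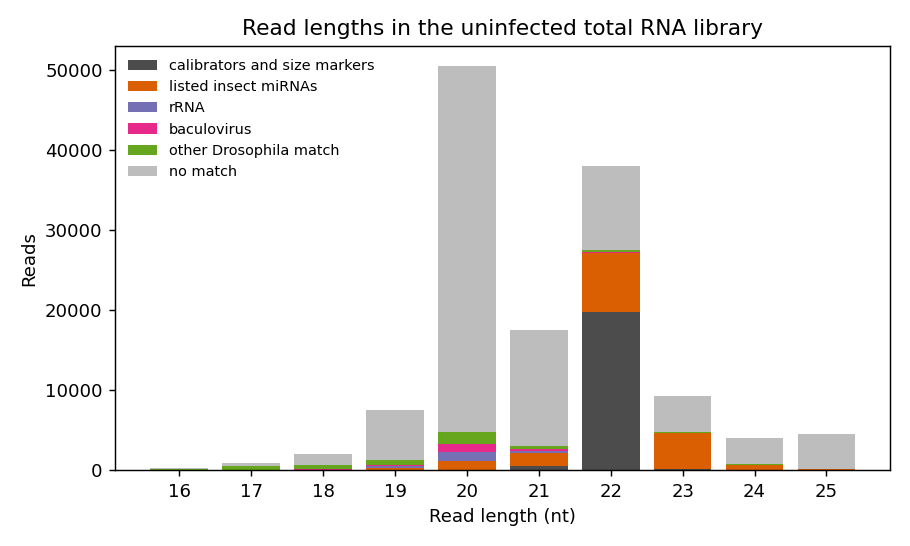
Reads at each length (nt) in the uninfected library, stacked by what they matched. The class of 20 nt, with 50506 reads, was mostly without a match, while calibrators and listed miRNAs made up most of the 37967 reads of 22 nt.

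At the 5' end, T (U in the RNA) was the most frequent base, with 49.2% (48.9 to 49.4) of the reads, then A with 21.3%, C with 18.9% and G with 10.7%. The miRNAs started with T in 80.7% (80.1 to 81.3) of reads, rRNA reads in 39.8% (37.5 to 42.1) and baculovirus reads in 42.6% (40.1 to 45.2), with A next at 36.6% in the latter. Among reads that were neither added oligonucleotides nor listed miRNAs, the share starting with T was 38.7% (38.3 to 39.2) at 20 nt, 44.4% (43.6 to 45.2) at 21 nt, 60.8% (59.9 to 61.7) at 22 nt, 43.7% (42.2 to 45.1) at 23 nt, 47.6% (45.9 to 49.3) at 24 nt and 60.8% (59.3 to 62.2) at 25 nt. Counted by distinct sequences, the shares were 37.3% at 20 nt, 44.3% at 21 nt and 48.9% at 22 nt. They were 50.2% at 23 nt, 53.5% at 24 nt and 62.5% at 25 nt, rising with length without a peak at 22 nt.

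Reads of other origin were sought with markers whose names were fixed before the data were examined and whose sequences were recalled afterwards. The mammalian miRNAs miR-21, miR-122, miR-16, miR-26, miR-155, miR-451, miR-143, miR-145, miR-17 and miR-20 had 0 reads. Reads that matched a baculovirus genome were found in this library of cells labelled as not infected, 1468 reads of 1376 distinct sequences, none read more than 8 times. Whether they come from virus is taken up below. Of the distinct sequences, 52.8% (50.1 to 55.4) lay on the plus strand and 47.2% on the minus strand of the virus record. All 27 bins of 5000 bases held at least 2 of them. The first bin and the last 2 bins held 545, or 39.6%, while the bins from 5001 to 55000 held 71, or 5.16%. With sequences of fewer than 10 reads left out, the baculovirus share was 0.

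**Figure D3:**
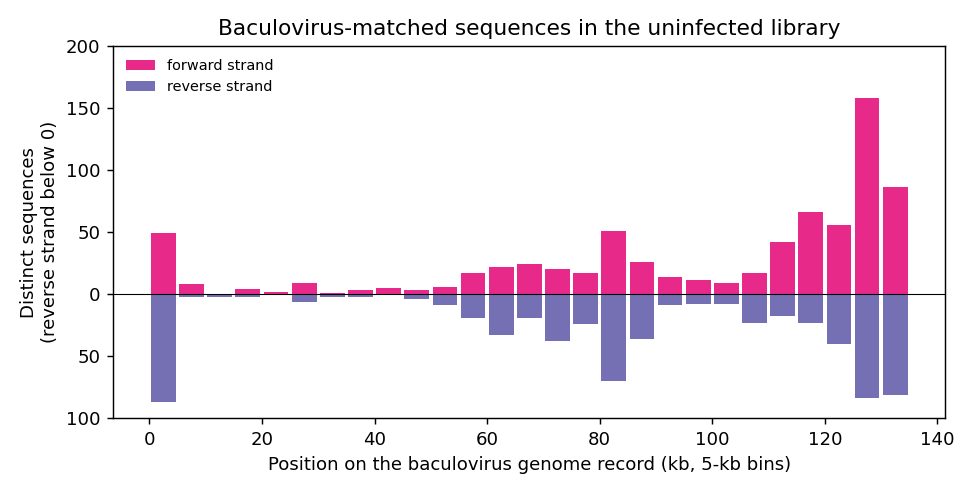
Distinct baculovirus-matched sequences in the uninfected library by position on the virus genome record (kb, bins of 5000 bases), with the plus strand above 0 and the minus strand below. Both strands were covered, with 242 sequences in the fullest bin and 2 in the emptiest.

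Opposite-strand pairs were counted among reads that matched no calibrator, size marker or listed miRNA, a measurement added after seeing the data. In animals, a 10-nt overlap of 5' ends is known from piRNAs, the small RNAs of Piwi proteins that silence transposons. Distinct reads of 23 to 25 nt formed 749 pairs with an overlap of 10 nt, against 54 at 11 nt and at most 26 at any overlap from 12 to 20 nt. The longest reads of the library were 25 nt, so longer RNAs could not be examined. The control, made with the complement without reversal, gave 27 pairs at 10 nt. An overlap of 9 nt was next in number, with 282 pairs against a control of 134. Reads of 20 nt formed 2718 pairs at 10 nt against a control of 1141, 1747 at 11 nt against a control of 320, and 1103 at 18 nt. On the rRNA gene record of Drosophila, 703 distinct reads lay on the rRNA strand and 521, or 42.6% (39.8 to 45.4), on the opposite strand. No test was made between the length classes, since pairs that share a read are not independent.

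**Figure D4:**
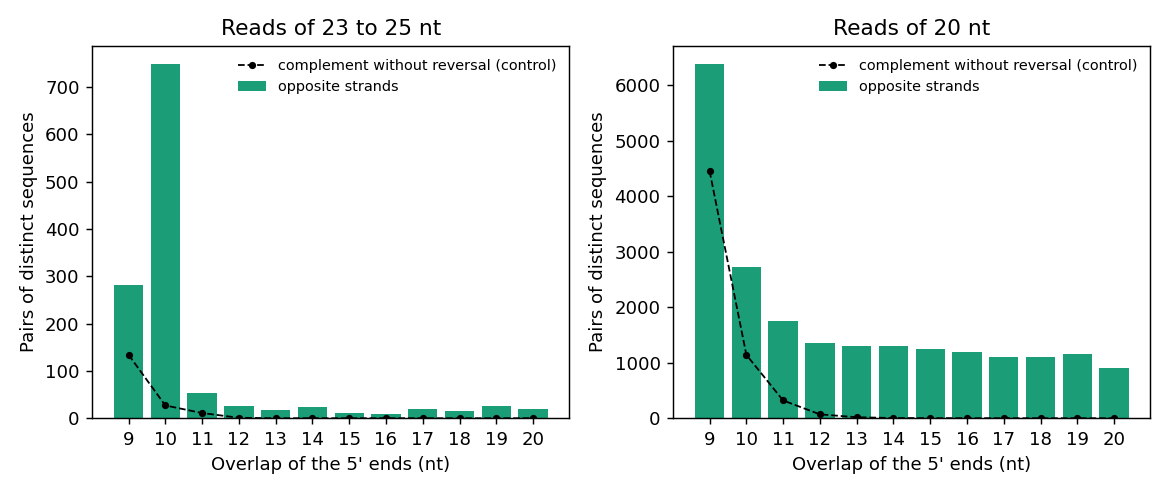
Pairs of distinct sequences whose 5' ends overlap by 9 to 20 nt on opposite strands (bars), for reads of 23 to 25 nt (left) and of 20 nt (right), with the control of unreversed complements as points. The longer reads stand at 749 pairs at 10 nt against 54 at 11 nt, while the 20-nt reads fall from 2718 to 1747.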

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

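All of these patterns were noticed in the data first. The tests on baculovirus and rRNA reads were chosen after the values they rest on, or a related profile, had been seen, while the leave-out test and the base 10 test of the 10-nt overlaps were set before their results were seen. The leave-out was first worded for a share of all reads and was run on paired reads only, a change made before the result.

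Baculovirus reads stood out because the cells are labelled as not infected, yet 1.09% of the reads matched a virus genome. Chance matches are argued against, since the 1376 distinct sequences were 572 times the 2.40 expected for reads of these lengths with 1 mismatch allowed. Sequence shared with a few moth genes is argued against as the whole source, since it would leave most of the virus record empty. All 27 bins of the record held matches, and 72.5% of 1380 virus matches had 0 mismatches. As a part of the source it stays open, since 39.6% lay in the first and last 2 bins and only a fly genome was searched. The fly genome was matched by 1.16% of the virus sequences and by 6.11% of all distinct sequences, so it decides nothing about the moth. Reads carried over from the infected libraries of the same lane, or virus present in these cells, remain open, because the infected libraries were not used here and the share of 1.09% cannot be told apart between these sources. Duplexes with 2-nt 3' overhangs could not be judged either, with 3 pairs at an 18-nt overlap and 0 to 6 at the other overlaps from 10 to 20 nt.

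rRNA reads stood out because 42.6% (39.8 to 45.4) of the 1224 distinct sequences on the rRNA gene record lay on the opposite strand, and 59.2% were 20 nt long. Breakdown of mature rRNA as the whole source is argued against, since it gives reads of the rRNA strand, and the 42.6% lies far above the 5% set as its limit. Duplexes with 2-nt 3' overhangs cannot be told apart from other pairings, with 66 pairs at 18 nt against 49 to 74 at the others. That prediction was set after the profile of all 20-nt reads, which has no peak at 18 nt, had been seen.

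Reads of 23 to 25 nt without a listed match stood out because 749 pairs of distinct sequences overlapped by 10 nt at their 5' ends, against 54 at 11 nt and a control of 27 at 10 nt. With no read over 25 nt in the library, these lengths do not show the full length range of the paired RNAs. A few inverted or repeated sequences are argued against as the whole cause. When the 90 of 905 paired sequences with the most partners were left out, 397 pairs remained at 10 nt against 48 at 11 nt, a ratio of 8.27. A candidate explanation is reciprocal cleavage by Piwi proteins, which pairs a first T with an A at base 10. Among 3332 distinct sequences that had no partner and did not start with T, base 10 was A in 41.6% (39.9 to 43.3), above the 24.6% to 29.3% at bases 8, 9, 11 and 12, which is consistent with it. It stays a hypothesis, since related sequences are not independent and no moth genome was used here.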

How the results depend on the processing

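No paired analysis was possible because 1 library was used. The 22 results had 84 alternatives, of which 25 stayed within the main value's 95% interval and 59 moved outside it. Some of the 25 could not move. The most abundant sequence is a calibrator, so leaving it out does not touch shares of miRNA reads. bantam is the only sequence of its family, and every hairpin passed the raised minimum for arms. Some of the 59 are only a change of denominator, so this tally is no measure of robustness. The 22 results are shares and carry no sign that could reverse, but some orders turned. The settings without calibrators and size markers and with 0 mismatches were chosen after seeing the data. Depth limits everything that rests on sequences read once, which the minimum of 10 reads removes. With that minimum, the share without a match became 75.1%, the Drosophila genome 24.9%, baculovirus 0 (from 1.09%), the 10 most abundant sequences 49.8%, 20 nt 5.92%, 22 nt 65.8%, first T 62.1%, listed miRNAs 30.8% and bantam 45.5% of miRNA reads. The lists became K box 8.86%, muscle 0, growth and survival 47.8%, ecdysone 4.02% and metabolic 2.09%. Without the most abundant sequence, no match became 85.5%, Drosophila genome 13.4%, the 10 most abundant 14.8%, 20 nt 38.9%, 22 nt 25.6%, first T 47.3% and listed miRNAs 12%. Without calibrators and size markers, no match became 83.5%, Drosophila genome 15.2%, baculovirus 1.29%, the 10 most abundant 10.3%, 20 nt 44.3%, 22 nt 16% and listed miRNAs 13.7%. With each distinct sequence counted once, no match became 92.1%, Drosophila genome 6.09%, baculovirus 1.76%, 20 nt 54.1%, 22 nt 7.99% and first T 41.9%. Split over the classes listed, Drosophila genome became 11.8%. With sequences of several classes left out, no match became 88.0% and Drosophila genome 10.9%. Without rRNA in the denominator, no match became 87.1% and Drosophila genome 11.8%. With 0 mismatches, listed miRNAs became 8.65%, bantam 56.0% of miRNA reads, and calibrators and size markers 13.9%. The lists then became let-7 complex 0.868%, K box 2.31%, Hox 11.9%, growth and survival 58.1%, ecdysone 5.12%, neuronal 2.04%, metabolic 3.44% and conserved insect 18.6%, so that K box fell below the Hox, ecdysone and metabolic lists and neuronal below metabolic. As shares of all reads, the lists became let-7 complex 0.147%, K box 1.09%, muscle 0.00297%, Hox 1.06%, growth and survival 5.30%, ecdysone 0.537%, neuronal 0.518%, metabolic 0.318% and conserved insect 2.95%, because of the larger denominator. Under the minimum of 10 reads, 22 nt rather than 20 nt was the leading length, the K box list fell below the Hox list at 9.18%, and the ecdysone list fell below the neuronal list at 4.17%. Leaving out sequences read only a few times removes most 20-nt reads by construction. Calibrators and size markers were nearly all without a match, and 95.8% of their reads were 22 nt long. Leaving them out therefore lowers the shares without a match and at 22 nt by construction as well. The cause of the other shifts was not tested.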

Other observations

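Of the tests in this part, the one on CCA ends was chosen after its result was seen, and the one on read errors was set before its result but could not decide.

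Above their controls the ratio of pairs at 10 nt to 11 nt was 1.11 at 20 nt, 1.36 at 21 nt, 2.56 at 22 nt and 16.8 at 23 to 25 nt. At 18 nt the 20-nt reads gave 1103 pairs, against a median of 1252 at the other overlaps from 12 to 19 nt.

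Reads ending in CCA, the sequence added to the 3' end of tRNAs, were 30.7% (27.8 to 33.8) of the 17-nt reads that matched no listed RNA, 9.83% (8.58 to 11.2) at 18 nt, 7.17% (4.16 to 11.4) at 16 nt, 5.50% (5.08 to 5.95) at 22 nt and 0.840% at 20 nt. Counted by distinct sequences the shares were 7.69% at 17 nt, 3.40% at 18 nt, 5.38% at 16 nt, 1.76% at 22 nt and 0.870% at 20 nt, and the 3 most abundant 17-nt sequences had 82, 80 and 43 reads. The most abundant of all were TCGATTCCCCGCCGGAGAGCCA with 196 reads and TCGATTCCCGGTATCGGAACCA with 138. They may be 3' ends of mature tRNAs, whose T arm often holds the bases TCGA. Of 95 distinct 22-nt sequences ending in CCA, 51 started with TCGA, 53.7% (43.2 to 64.0), against 36 of 5288 others, 0.681%. Fisher's exact test over distinct sequences, two-sided, gave p = 7.01e-73. The TCGA start was chosen after these sequences had been seen, and sequences of 1 tRNA are not independent. The p-value is therefore no measure of support. The fly annotation lists neither of these 22-nt sequences.

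Of the 71439 sequences read once, 565, or 0.791% (0.727 to 0.859), were 1 substitution from a sequence with at least 100 reads. The sequences with at least 100 reads number 49 and have at most 3222 such neighbours, 4.51% of the sequences read once, so the outcome was fixed in advance and the share that comes from read errors stays open. The calibrators gave 3251 reads of 22 nt with 1 substitution beside 16764 exact reads, or 7.38 substitutions per 1000 bases. G to A made up 32.8% of these, and position 21, counted from 1 at the 5' end, had 42.7 per 1000 exact reads. Of the 715 reads changed at position 21, 207 were G to T in calibrator 10, or 8.77% of its exact reads. The most frequent change there in calibrator 3, C to A, was 2.10% of its exact reads. The pooled value is therefore not a rate shared by all calibrators. The 3251 reads include changes in bases 2 to 8, which the match rule leaves out of the calibrator total given above.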
